A study of Nicotiana attenuata with 18 samples.

How the data were processed

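Floral peduncles of wild-type Nicotiana attenuata, a wild tobacco, were cut lengthwise along the midline into an adaxial side, which faces the stem axis, and an abaxial side, which faces away. They were collected at zeitgeber times 0, 6 and 14, written ZT0, ZT6 and ZT14, in a cycle of 16 h light and 8 h dark, so that all 3 samplings fell between lights-on and lights-off. Each of the 6 groups held 3 replicates, and each of the 18 replicates was a pool of several peduncle sides, per the labels' protocols. The p-values therefore measure the spread between pools, not between single plants. Each pool was labelled with Cy3 and hybridised to its own 1-colour Agilent array.

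The scanner files hold spot intensities on a linear scale, which were extracted and background-corrected with Agilent Feature Extraction, per the file headers. The headers name version 10.7.3.1 in all files and the submitters' processing notes name version 9.5; both are given here as stated. The flags for spots well above background and for outliers are the scanner software's own yes-or-no calls, an "other" kind of value deposited in the same files, per the file headers. The authors also deposited a table of log2 values for the same arrays. Set against the scanner files, each column of that table equalled the log2 processed signal minus that array's 75th percentile: 100% of single-spot probes lay within 0.011 of one constant per array. Column medians ran from -4.36 to -4.1 and every 75th percentile was 0, so scale, centring and direction are known. According to the series' design text, the authors kept probes well above background in all replicates of at least 1 condition and raised signals below 1 to 1. They then compared the sides with the BETR method in MeV, which was not used here.

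For the values analysed here, the processed signal was raised to at least 1 and put on the log2 scale. Control spots and spots with an outlier flag were left out, spots of a probe were averaged, and the 75th percentile over the array's 59157 probes was subtracted. A level of 0 is thus the 75th percentile of an array, and levels of different probes are not compared. The 75th percentile itself ran from 7.30 to 8.20 log2 units over the 18 arrays, and 45.24% to 53.22% of probes were well above background on an array. Probes well above background on all 3 arrays of at least 1 group were kept, which left 30714. Precision is limited by the number of arrays.

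All 6 groups were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8) and jsonlite 2.0.0 for reading the files, and matplotlib 3.10.9 under Python 3.11.15 for the plots. Side contrasts are adaxial minus abaxial at each time and on average over the 3 times, time contrasts are the later minus the earlier time averaged over both sides, and moderated F-tests asked whether the sides differed at any time and whether the side difference depended on time. The Benjamini-Hochberg adjusted p had to lie under 0.05 over all probes kept. A fold is 2 to the power of the log2 difference. For a probe well above background on no array of 1 group, the fold is given as a lower bound, "at least", taking for each dim array the higher of its lowest signal among probes well above background and the probe's own signal. No fold is given where neither group was well above background. Where only some arrays of a group were, their number is given beside the fitted fold, and where they were under 50% of the group, a log2 difference in place of the fold. On simulated data for these 30714 probes with 200 changed, the fit recovered 10.4%, 58.2% and 92.4% of changes of 0.5, 1 and 2 log2 units for the sides at ZT0. The shares were 17.9%, 68.7% and 93.9% at ZT6 and 17.9%, 52.2% and 95.5% at ZT14. They were 29.9%, 79.1% and 98.5% for ZT6 against ZT0, and 2.99%, 23.9% and 75.8% for the dependence on time. Unchanged probes made up 5.31%, 0.826%, 9.09%, 4.17% and 4.23% of the calls in those 5 comparisons. The simulated noise was independent between arrays, without the correlation of pairs or slides, and most real contrasts called far more than 200 probes. These shares therefore do not give the recovery or the false calls of the real contrasts.

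Probes were named from the homologue label in the scanner files. Of the 59157 probes, 37327 carried no homologue, 13034 a protein accession alone, 4962 a potato and 3470 a tomato genome identifier, and 364 a readable UniProt entry name, such as RCA_SOLPN. None of the probe identifiers matched the 39977 genes of the reference table. An entry name is that of the homologue, with a code for its species at the end, and not of a N. attenuata gene. Among the 30714 probes kept, 211 had an entry name, and 206 of these named a characterised protein. The genome annotation that the study used was not used here. Clock genes and Aux/IAA genes, which were to be reported whatever their result, were not analysed here. None of the readable entry names is one of theirs, and the protein accessions and genome identifiers, which may stand for some of them, were not resolved to names, as no table for this was held.

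Before the data were examined, the comparisons, the alternatives, the rule for naming probes and 36 gene lists were fixed. The rule took, for each contrast and direction, up to 6 entry names with the largest change among probes past the threshold whose groups did not overlap, with 1 probe per name, plus up to 4 members of each tested list. For the average over times the sign had to be the same at all 3 times. Of the 36 lists, 21 had no labelled probe, among them those for auxin, the clock and organ polarity. Those with at least 3 measured members were heat shock proteins, with 3, and photosynthesis light harvesting and photosystems, with 5. A member of the latter, PSA6_TOBAC, is a proteasome subunit that the list's name pattern took in. A further 14 groups were made from the probe labels after these were read but before any value was looked at, and 11 of them had at least 3 measured members. Lists and groups were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation, using for each entry name the probe of highest mean signal. Members are entry names and not separate genes. Among the plastid- and mitochondrial-genome members several entry names give the same protein in different species, such as RK22, RK14 and RT14. Counts of members and their p-values are thus not over independent genes. Adjustment was made over lists and 7 contrasts, separately for the lists and for the label groups, 91 tests in all.

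The arrays lay on 4 slides, each scanned in its own session. Slide 1 held adaxial ZT6 replicates 1 and 2 and abaxial ZT6 replicate 1. Slide 2 held all adaxial ZT0 arrays, adaxial ZT6 replicate 3, abaxial ZT0 replicate 1 and abaxial ZT6 replicates 2 and 3. Slide 3 held all 6 ZT14 arrays and abaxial ZT0 replicate 2, and slide 4 held abaxial ZT0 replicate 3 alone. ZT14 shares a slide with another time only through 1 array, so with slide as a block its comparison with ZT0 and ZT6 rests on that array. The labels number the replicates 1 to 3 in each group. Deviations from the group means of same-numbered adaxial and abaxial arrays correlated across probes at 0.219 to 0.489 at ZT0 and 0.343 to 0.634 at ZT14, so the numbers were taken to pair the sides at these times. That the pairing was judged for each time was settled after the blocked counts had been seen. At most 1 probe held an identical value on 2 arrays of a group, and correlations between replicates lay between 0.974 and 0.992.

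The alternatives were normexp background correction with an offset of 50, run on median spot and background signals since those columns hold them, quantile normalization, the percentile over probes detected on all arrays, a floor, the authors' table and other filters. Further ones were array weights, only the groups compared, a stricter threshold, a 2-fold minimum, slide and replicate number as blocks, each slide alone and each array left out in turn. Named probes were refitted under normexp, quantile normalization, the blocks for slide, replicate number and pair, without the 3 arrays of lowest signal and with each array left out. A block for each pair within a time, run for named probes and for the lists between the sides too, the pairs at ZT0 and ZT14 as a random block, splits of the arrays that follow these pairs, and the fit without the 3 arrays of lowest 75th percentile (abaxial ZT0 replicates 1 and 2 and abaxial ZT6 replicate 3), were chosen after seeing the data.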

Results

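The study follows the daily movement of tobacco flowers, in which the peduncle bends as its sides grow unequally. Transcript levels were measured in the adaxial and the abaxial side of the peduncle at ZT0, ZT6 and ZT14, on 3 arrays per side and time, 18 in all. Values are log2 signals relative to each array's 75th percentile, given as mean ± SD with n = 3 for a side at a time unless stated otherwise. Adjusted p-values are from limma.

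Time of day separated the arrays most, and the sides stood apart at ZT6. Over the 30714 probes kept, the first principal component held 43.8% of the variance and the second 25%. On the first, the adaxial ZT6 arrays lay between 78.38 and 90.52 and the abaxial ZT6 arrays between 32.65 and 41.96. At ZT14 the order was the opposite, with adaxial arrays between 17.69 and 37.78 and abaxial arrays between 41.15 and 53.51. The sides overlapped at ZT0, with adaxial arrays between -109.6 and -85.15 and abaxial arrays between -108.9 and -87.36.

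**Figure D1:**
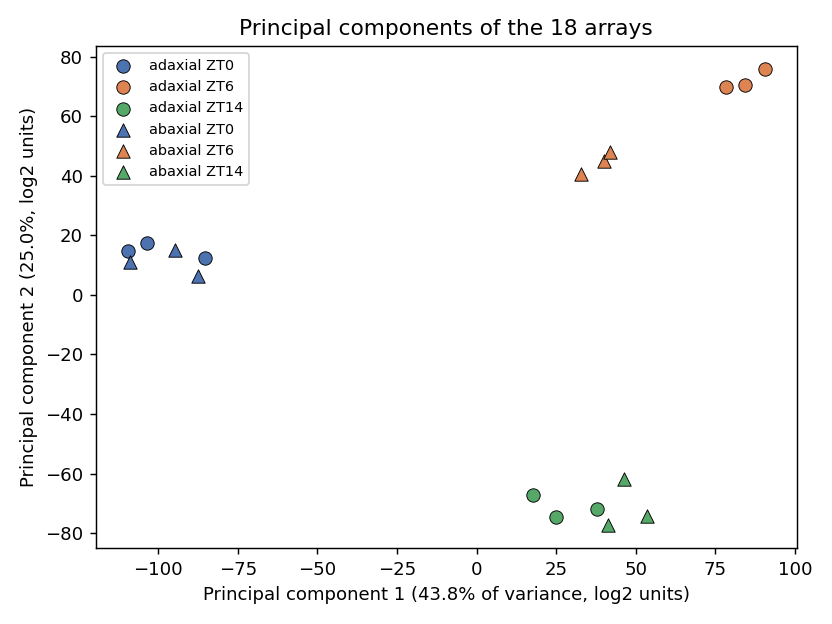
Each point is 1 of the 18 arrays, placed by its scores on principal components 1 (43.8% of variance) and 2 (25%), in log2 units; circles are adaxial, triangles abaxial, and colour gives the time. The 3 times form separate clusters, and the sides lie apart at ZT6 and overlap on the first component at ZT0.

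At ZT6 an enzyme of sesquiterpene phytoalexin synthesis had higher signal in the adaxial side. 5EAS1_NICAT, an epi-aristolochene synthase, was 4.94-fold higher (log2 difference 2.30, SE 0.251, adjusted p 1.67e-05), at -1.43 ± 0.165 on the adaxial and -3.73 ± 0.232 on the abaxial side, where 2 of 3 arrays were well above background. C71DK_TOBAC, the cytochrome P450 that acts on its product, was well above background on the adaxial side alone and at least 1.35-fold higher there (log2 2.43, adjusted p 0.000313), but with normexp background correction its difference was 0.15 and did not pass (adjusted p 0.541). PDR1_TOBAC, an ABC transporter of the pleiotropic drug resistance family, was 2.92-fold higher (log2 1.55, SE 0.273, adjusted p 0.00111). ABAH4_ARATH, an abscisic acid hydroxylase, was well above background on the adaxial arrays alone and at least 3.27-fold higher (log2 2.50, adjusted p 0.000964), and with normexp its difference of 0.39 did not pass (adjusted p 0.0645).

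Photosynthesis proteins encoded in the nucleus were shifted to the abaxial side at ZT6 as a group, by a test that assumes little correlation between them. Of 11 measured members of this label group 4 were lower adaxially, 7 did not pass, and the median log2 difference was -0.565 (camera adjusted p 0.00965; adjusted p = 0.82 with an estimated correlation). RCA_SOLPN, Rubisco activase, was 3.18-fold higher abaxially, at 4.37 ± 0.386 against 2.70 ± 0.0795 (log2 -1.67, SE 0.302, adjusted p 0.00132). CB23_TOBAC, a chlorophyll a/b-binding protein, was 1.76-fold higher abaxially (adjusted p 0.0106), and PSAEA_NICSY, a photosystem I subunit, 1.70-fold (adjusted p 0.0144). The remaining member of the 4, NDHM_VITVI, a subunit of the chloroplast NAD(P)H dehydrogenase complex, passed the test at log2 -1.79 (adjusted p 0.0039), but was well above background on none of these 6 arrays, and with normexp did not pass (log2 -0.34, adjusted p 0.061). SNAK1_SOLTU, an antimicrobial peptide of the snakin family, was 2.0-fold higher abaxially (adjusted p 0.00093), and the sugar carrier STA_RICCO 1.51-fold (adjusted p 0.0208).

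Cytosolic ribosomal proteins were shifted to the adaxial side at ZT6 as a group, by the same test. Of 8 measured members 3 passed, all adaxially higher, 5 did not, and the median difference was 0.541 (camera adjusted p 0.00252; adjusted p = 0.82 with an estimated correlation). Those past the test, each by its brightest probe, were RS3A_TOBAC, 1.70-fold (adjusted p 0.0145), RL15_PETHY, 1.56-fold (adjusted p 0.0183), and RS4_SOLTU, 1.45-fold (adjusted p 0.00952). RL8_SOLLC was 1.90-fold higher by a dimmer probe (log2 0.93, SE 0.197, adjusted p 0.00433), and its brightest probe did not pass (log2 0.38, adjusted p 0.0816). In the group of 8 defence enzymes and peptides, 3 members were higher adaxially (5EAS1_NICAT, C71DK_TOBAC and PDR1_TOBAC) and SNAK1_SOLTU was lower, and the group as a whole did not pass (adjusted p 0.19). Median differences within slide 1 and slide 2 were 0.467 and 0.512 for the ribosomal proteins and -0.573 and -0.572 for the photosynthesis proteins. For the defence group they were 0.673 and 0.308. Single ZT6 arrays also ended calls. RS3A_TOBAC had an adjusted p of 0.0564 without adaxial replicate 2 and 0.051 without abaxial replicate 3, and PSAEA_NICSY 0.0592 without adaxial replicate 1 and 0.062 without abaxial replicate 3. STA_RICCO had 0.0575, 0.0774, 0.0561 and 0.0943 without adaxial replicates 2 and 3 and abaxial replicates 1 and 2.

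Over all probes, 5326 of 30714 differed between the sides at ZT6, 2633 higher adaxially and 2693 higher abaxially, and 1949 of them by at least 2-fold. Groups did not overlap for 11489 probes, where chance gives 10%. Of the 206 named probes 22 passed, 13 higher and 9 lower. With the sides blocked by pair 41 passed, 23 higher and 18 lower, though the ZT6 sides were not taken as paired. Among probes well above background on all 6 arrays, those with the largest changes carry no readable name: NA6144_44816 was 30.56-fold higher adaxially (adjusted p 1.6e-06) and C644196 38.7-fold higher abaxially (adjusted p 3.23e-07). Within slide 1 alone 1772 probes passed, 1136 higher adaxially and 636 higher abaxially, within slide 2 alone 668, and with slide as a block 4913. Without adaxial ZT6 replicate 2 the count fell to 3538.

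**Figure D2:**
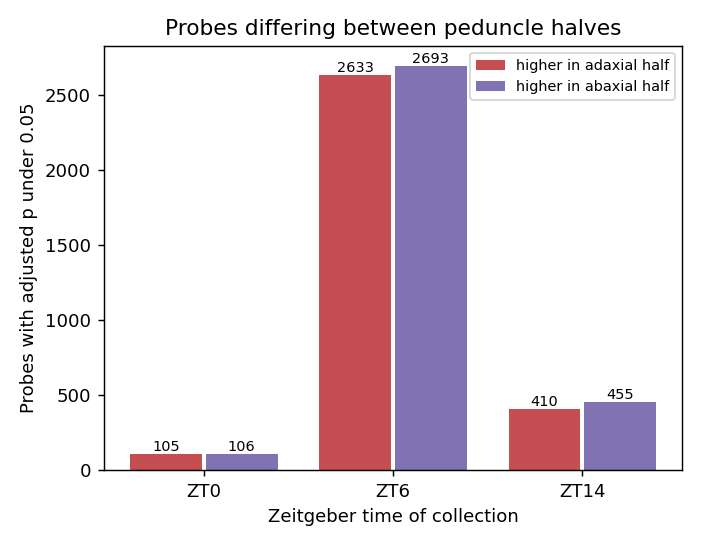
Bars give the number of probes, of 30714, with an adjusted p under 0.05 between the sides at each time, split by the side of higher signal. The counts were 105 and 106 at ZT0, 2633 and 2693 at ZT6, and 410 and 455 at ZT14 (adaxial and abaxial).

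At ZT14 Rubisco activase was on the other side. RCA_SOLPN was 3.22-fold higher adaxially, at 2.86 ± 0.41 against 1.18 ± 0.487 (log2 1.69, SE 0.302, adjusted p 0.00671). CATA3_NICPL, a catalase, was 1.86-fold higher adaxially (log2 0.89, SE 0.107, adjusted p 0.000359), and both of its probes passed. MATK_POPAL, the plastid intron maturase, was 1.84-fold higher adaxially (adjusted p 0.0116), the chloroplast transketolase TKTC_SOLTU 1.65-fold (adjusted p 0.0462) and the proteasome regulatory subunit PSMD3_TOBAC 1.56-fold (adjusted p 0.026). The transporter PDR1_TOBAC was the single named probe higher abaxially, 2.18-fold (log2 -1.13, SE 0.273, adjusted p 0.0394).

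Proteins encoded in the plastid genome were shifted to the adaxial side at ZT14 as a group, by the test that assumes little correlation between members. The median of the 48 measured members was 0.283 (camera adjusted p 2.44e-06; adjusted p = 0.82 with an estimated correlation), with 2 members past the test, MATK_POPAL and the open reading frame YCF68_SACOF, and 46 not. The 11 nuclear photosynthesis proteins had a median of 0.265 (camera adjusted p 0.0189; adjusted p = 0.82 with an estimated correlation), and RCA_SOLPN alone passed. No other label group passed at ZT14, and the 8 ribosomal proteins had a median of -0.0993.

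In all, 865 of 30714 probes differed at ZT14, 410 higher adaxially and 455 higher abaxially, 387 by at least 2-fold, and groups did not overlap for 6626. The 10% that chance gives for independent arrays may not hold here, as the sides were taken as paired. Of the 206 named probes 7 passed, 6 higher and 1 lower, and 12 with the sides blocked by pair, 7 and 5. With the pairs as a random block 20 of them passed, 12 higher and 8 lower. All ZT14 arrays lay on slide 3, where 327 probes passed in a fit of that slide alone. With the sides blocked by pair the count over all probes was 2044, and with the pairs as a random block 3339. Without the 3 arrays of lowest signal, none of them from ZT14, it was 1488. It was 368 without adaxial replicate 2, 510 without adaxial replicate 3, and 502, 555 and 434 without abaxial replicates 1, 2 and 3. TKTC_SOLTU and PDR1_TOBAC each lost their call in 14 of the alternatives (highest adjusted p 0.19 and 0.181), which leave out single arrays of any time and, for PDR1_TOBAC, set slide as a block (0.0595). PSMD3_TOBAC lost its call without any ZT14 array but adaxial replicate 3 (highest 0.12), and MATK_POPAL without adaxial replicate 2 (0.0634) or abaxial replicate 3 (0.0643).

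At ZT0 none of the 206 named probes passed limma's test between the sides without a block for pairs, and 15 had an unadjusted p under 0.05. With the sides blocked by pair 2 passed. CATA3_NICPL was higher adaxially by 0.46 (adjusted p 0.0286 with the block and 0.0722 without). The other was the plastid ribosomal protein RR3_OENEH, well above background on the adaxial arrays alone (0.0397 and 0.13). With the pairs as a random block 6 passed, these 2 among them. RCA_SOLPN stood at 5.41 ± 0.301 adaxially and 5.03 ± 0.547 abaxially, 5EAS1_NICAT was well above background on no array of either side, and PDR1_TOBAC stood at -1.09 ± 0.0827 and -0.79 ± 0.295. No list or label group passed with all arrays and no block. Pollen proteins passed with the block for pairs (median -1.18, adjusted p 0.049), chaperones within slide 2 alone, with its 1 abaxial ZT0 array (0.507, adjusted p 0.0293, against 0.348 with all arrays), and mitochondrial-genome proteins without the 3 arrays of lowest signal (-0.202, adjusted p 0.0321, against a median of 0.0107 with all arrays). With an estimated correlation, all arrays and no block, these 3 groups had adjusted p = 0.834, 0.934 and 0.988. Over all probes 211 passed, 105 higher adaxially and 106 higher abaxially, and 2608 had an unadjusted p under 0.05. Groups did not overlap for 4074 of 30714 probes. Chance gives 10% for independent arrays, which paired sides are not.

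The ZT0 count depended on single arrays, and the fits by slide rested on 1 abaxial array. It was 105, 110 and 130 without adaxial replicates 1, 2 and 3, and 50 in a fit of the ZT0 arrays alone. With slide as a block, as within slide 2 alone, the ZT0 side contrast rests on abaxial ZT0 replicate 1. The other abaxial ZT0 arrays lie on slides that hold no adaxial ZT0 array. The median difference of the chaperones was 0.507 in both fits, against 0.16 with all arrays. Neither fit can tell an effect of slide from that of 1 array. With the sides blocked by pair 627 passed, 243 higher adaxially and 384 higher abaxially. Without the 3 arrays of lowest signal, which leaves 1 abaxial array that is assumed to vary like the other groups, 1003 passed, 709 and 294. The even split between the directions thus did not hold with the block for pairs or without these 3 arrays.

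The side difference itself depended on time for 2713 probes in the fit without a block for pairs. With the sides blocked by pair 4824 passed, and with the pairs at ZT0 and ZT14 as a random block 4709. RCA_SOLPN (adjusted p 0.000469) and PDR1_TOBAC (0.00113) were each past the test in opposite directions at ZT6 and ZT14. 5EAS1_NICAT (0.000571) was higher adaxially at ZT6 and differed by 0.13 at ZT14, which did not pass (adjusted p 0.941). The side difference also depended on time for C71DK_TOBAC (0.00617), SNAK1_SOLTU (0.00564), CATA3_NICPL (0.00755), ABAH4_ARATH (0.0221) and MATK_POPAL (0.0446). For CATA3_NICPL this rests on its brighter probe, as its dimmer one did not pass (adjusted p 0.51 by the moderated F-test).

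**Figure D3:**
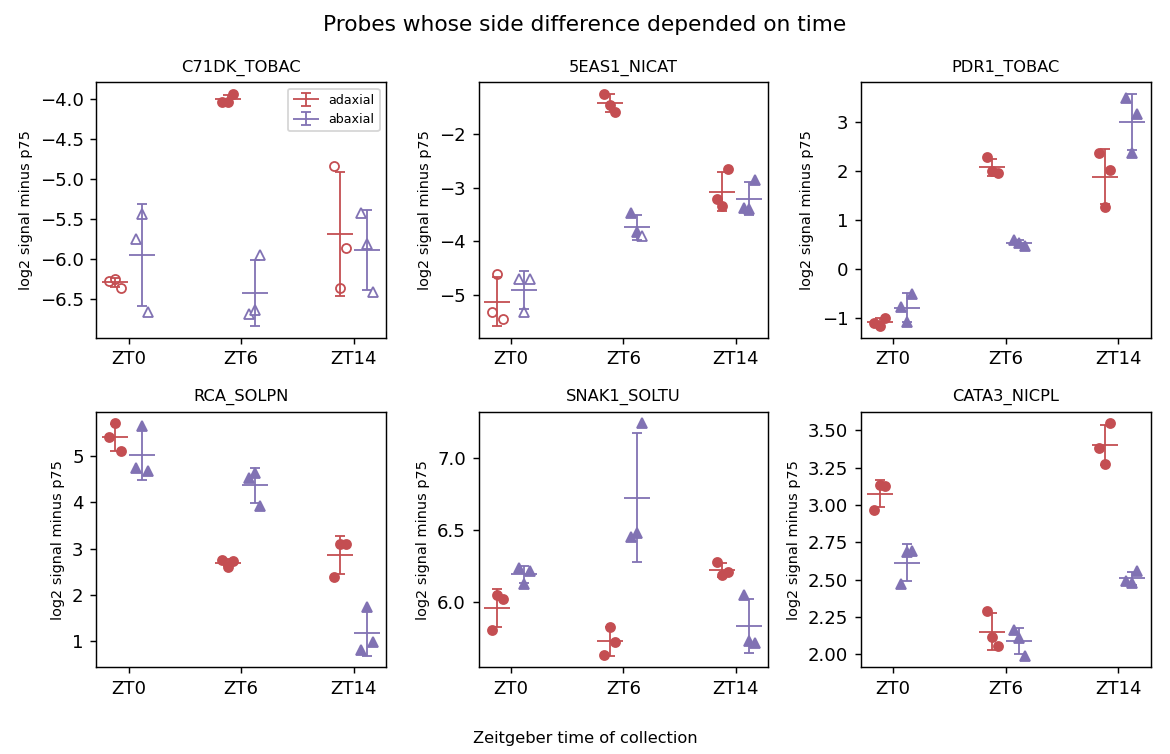
Log2 signal relative to the array's 75th percentile of the 6 named probes whose side difference depended on time at an adjusted p under 0.01; each point is 1 array, filled where well above background, with the mean and SD of the 3 arrays. Circles are adaxial and triangles abaxial. CATA3_NICPL is shown by its brighter probe. RCA_SOLPN was higher abaxially at ZT6 and adaxially at ZT14.

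Of the 2713 probes, 2024 were past the test at ZT6 alone, 220 were past it in opposite directions at ZT6 and ZT14, and 145 at no single time. The side difference at ZT6 differed from that at ZT0 for 1569 probes and from that at ZT14 for 3667, while ZT14 and ZT0 differed for 4. These counts are from the fit without a block for pairs. Calls at ZT6 and ZT14 had 112 probes in common that were higher adaxially and 119 higher abaxially, where independent lists would share 35.1 and 39.9, and 220 opposite, where they would share 75. Without adaxial ZT6 replicate 3, 1744 probes passed the test of dependence on time, and without the 3 arrays of lowest signal 4829.

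Averaged over the 3 times, CATA3_NICPL was 1.46-fold higher adaxially by its dimmer probe (log2 0.54, SE 0.114, adjusted p 0.00691). PSMD3_TOBAC was 1.34-fold higher (adjusted p 0.00437), TKTC_SOLTU 1.33-fold (adjusted p 0.0211) and the mitochondrial ribosomal protein RT14_OENBE higher by log2 0.50 (adjusted p 0.0295; well above background on 7 of 9 adaxial and 4 of 9 abaxial arrays). Higher abaxially were glutamine synthetase GLNA_NICPL, 1.29-fold (adjusted p 0.0105), thioredoxin TRXH2_TOBAC, 1.25-fold (adjusted p 0.00487), the cytochrome b5 CYB5S_TOBAC, 1.27-fold (adjusted p 0.0153), the starch-phosphorylating GWD1_SOLTU, 1.25-fold (adjusted p 0.0294), and NDHM_VITVI, by log2 0.86 (adjusted p 0.0226), which was well above background on 1 of 9 adaxial and 4 of 9 abaxial arrays. In all 2657 probes passed, 1172 higher adaxially and 1485 higher abaxially, a balance that turned to 1820 and 1456 without the 3 arrays of lowest signal, and 13 of the 206 named probes, 8 higher and 5 lower. With the sides blocked by pair 22 named probes passed, and the ribosomal proteins as a group did (median 0.147, adjusted p 0.0495, against 0.13 without the block; adjusted p = 0.922 with an estimated correlation and no block). The test of a difference at any time, which asks the question of the study's own time-course test, gave 4375 probes. GWD1_SOLTU lost its call in 12 alternatives (highest adjusted p 0.096), RT14_OENBE in 10 (0.989, under normexp) and NDHM_VITVI in 4 (0.138). CYB5S_TOBAC lost it with slide as a block alone (0.086).

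From ZT0 to ZT6, transcripts of the plastid and mitochondrial genomes fell and those of chaperones and cytosolic ribosomal proteins rose, in the mean of both sides (n = 6 at each time). Here and below n = 6 counts arrays, which are not independent at ZT0 and ZT14, where the sides were taken as paired. The p-values between times are from the fit without a block for pairs. With these pairs as a random block fewer probes passed between times. The counts were 19183 for ZT6 against ZT0, 14053 for ZT14 against ZT6 and 14999 for ZT14 against ZT0. Of 48 measured plastid-genome members 44 fell, 3 did not pass and 1, PSBC_TRACE, rose by 0.19, with a median of -1.15 (camera adjusted p 2.7e-12; adjusted p = 0.541 with an estimated correlation). RK14_LOTJA, a plastid ribosomal protein, was 7.0-fold lower (adjusted p 1.54e-09), RPOB_NICSY, a subunit of the plastid RNA polymerase, 5.52-fold (adjusted p 2.81e-08; well above background on 4 of 6 ZT6 arrays) and RR15_SOLTU, another plastid ribosomal protein, 4.09-fold (adjusted p 1.28e-08). Of 12 mitochondrial-genome members 11 fell and 1 did not pass, with a median of -1.42 (camera adjusted p 0.000417; adjusted p = 0.82 with an estimated correlation).

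All 5 chaperones rose from ZT0 to ZT6 (median 1.08, camera adjusted p 0.0254; adjusted p = 0.82 with an estimated correlation), among them BIP5_TOBAC of the endoplasmic reticulum, 3.42-fold (adjusted p 5.84e-07). All 8 ribosomal proteins rose (median 0.574, camera adjusted p 0.0323; adjusted p = 0.834 with an estimated correlation). 5EAS1_NICAT, well above background on none of the ZT0 and 5 of 6 ZT6 arrays, rose by at least 3.05-fold (adjusted p 2.46e-08), PDR1_TOBAC 4.75-fold (adjusted p 1.25e-07), the chlorophyll-binding CB23_SOLLC 3.56-fold (adjusted p 2.6e-08) and the small GTPase YPT3_NICPL 3.34-fold (adjusted p 1.73e-08). UGPA_SOLTU, a UTP-glucose uridylyltransferase, rose 4.14-fold by 1 probe (adjusted p 1.6e-06), well above background on 4 of 6 ZT0 arrays, while its brighter probe did not pass (log2 -0.09, adjusted p 0.397). POLX_TOBAC, a retrotransposon polyprotein, fell 5.76-fold (adjusted p 4.77e-08), and NDHM_VITVI, well above background on 4 of 6 ZT0 and none of the ZT6 arrays, at least 1.90-fold (adjusted p 4.18e-06).

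The list of heat shock proteins fixed beforehand had 3 of 3 members rise from ZT0 to ZT6 and fall to ZT14, adjusted over the list alone and over all probes, but as a list it did not stand apart from other probes (camera adjusted p 0.249 and 0.207). Of the 5 members of the light-harvesting and photosystem list, 3 rose, 1 fell and 1 did not pass from ZT0 to ZT6, against 4 past the test when adjusted over the list alone, and the list did not pass in any contrast (lowest adjusted p 0.411). Neither list passed in any of 14 tests, of which 2 had an unadjusted p under 0.05.

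In all, 20455 probes differed between ZT6 and ZT0, 10504 higher at ZT6 and 9951 lower, a balance that turned to 8907 and 10415 with normexp, including 148 of the 206 named probes. Slide 2, which held both times, gave 13640 probes alone and medians of -1.23 for the plastid genome, -1.41 for the mitochondrial genome, 1.24 for chaperones and 0.600 for ribosomal proteins. With quantile normalization the chaperone and ribosomal shifts did not pass (adjusted p 0.0608 and 0.131), and with slide as a block the ribosomal shift did not (0.0529).

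**Figure D4:**
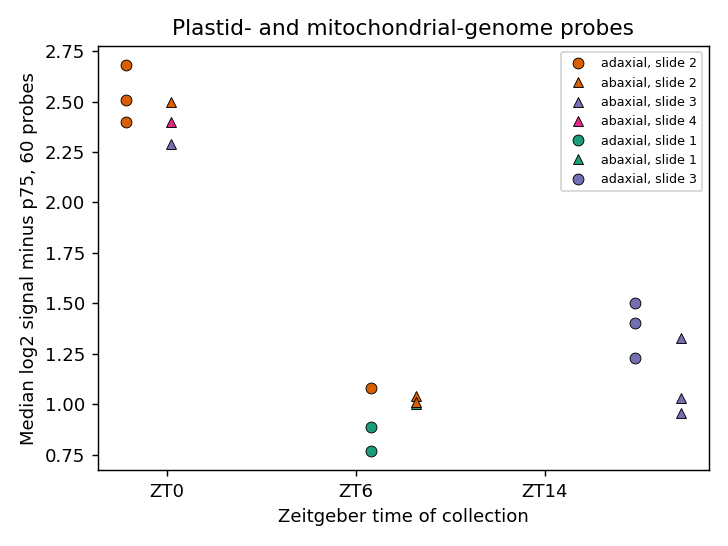
Each point is the median log2 signal, relative to the array's 75th percentile, of the 60 plastid- and mitochondrial-genome probes on 1 array, by time of collection; circles are adaxial, triangles abaxial, and colour gives the slide. All 6 ZT0 arrays lie above all arrays of the later times, also among the arrays of slide 2.

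From ZT6 to ZT14 the 2 chlorophyll-binding proteins with the largest changes fell to a small part of their signal. CB23_TOBAC fell 17.18-fold, from 6.37 ± 0.459 to 2.27 ± 0.293 (SD, n = 6; adjusted p 1.25e-11), and CB23_SOLLC 15.55-fold (adjusted p 1.14e-11). GWD1_SOLTU, which acts in starch breakdown, rose 4.67-fold (adjusted p 3.91e-10) and the pentatricopeptide repeat protein PPR85_ARATH 2.43-fold (adjusted p 2.79e-07). All 5 chaperones fell (median -1.33, camera adjusted p 0.00965; adjusted p = 0.82 with an estimated correlation), and 7 of 8 ribosomal proteins fell (median -0.51, camera adjusted p 0.022; adjusted p = 0.834 with an estimated correlation, and 0.124 with quantile normalization). In total 15788 probes differed, 7411 higher at ZT14 and 8377 lower, a balance that turned to 8191 and 7397 with quantile normalization.

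These times share no slide and are linked by 1 array, and with slide as a block 3077 probes passed. Some named probes were past the test without the block and in every other alternative run for named probes, but not with it. Those that rose were the peptide and nitrate transporter family member PTR16_ARATH (log2 2.49, well above background on 1 of 6 ZT6 arrays, adjusted p 0.129 with the block), C76A1_SOLME, a cytochrome P450 (5.20-fold up, 0.334), IFRH_SOLTU (2.23-fold up, 0.0899) and RK14_SOYBN (2.07-fold up, 0.0654). Those that fell were ABAH4_ARATH (at least 1.28-fold, 3 of 6 ZT6 and none of the ZT14 arrays well above background, 0.0817), the carbonic anhydrase CAHC_TOBAC (3.83-fold, 0.267), UGPA_SOLTU (3.21-fold, 5 of 6 ZT14 arrays well above background, 0.242) and BIP_SOLLC (3.19-fold, 0.057).

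Between ZT0 and ZT14, transcripts of nuclear photosynthesis proteins and of the plastid genome fell. RCA_SOLPN was 9.17-fold lower at ZT14, at 2.02 ± 1.01 against 5.22 ± 0.446 (SD, n = 6; adjusted p 1.17e-08), CB23_TOBAC 7.65-fold (adjusted p 2.83e-10), CB23_SOLLC 4.37-fold (adjusted p 6.23e-09) and CAHC_TOBAC 5.67-fold (adjusted p 0.000453). Of the 11 nuclear photosynthesis proteins 8 fell and 3 did not pass (median -1.08, camera adjusted p 0.0189; adjusted p = 0.82 with an estimated correlation); the group also holds FENR2_TOBAC, a ferredoxin reductase of the root type, which fell 2.12-fold. The light-harvesting and photosystem list fixed beforehand did not pass (median 0.0959, camera adjusted p 0.983); 2 of its 5 members, PSBK_SILLA and PSBC_TRACE, fell, the proteasome subunit PSA6_TOBAC rose and 2 did not pass. All 48 plastid-genome members fell, several of them entry names of the same gene (median -1.02, camera adjusted p 1.46e-12, and 0.541 with an estimated correlation). Most of them are ribosomal proteins or others outside photosynthesis. RK14_LOTJA fell 3.62-fold, and 10 of 12 mitochondrial-genome members fell (median -1.01, camera adjusted p 0.00094, and 0.82 with an estimated correlation). With slide as a block the medians were -1.24, -0.888 and -0.771, and without the 3 arrays of lowest signal the nuclear photosynthesis shift did not pass (adjusted p 0.0772).

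Among the named probes higher at ZT14 than at ZT0, C76A1_SOLME rose 15.09-fold (adjusted p 1.23e-06), PDR1_TOBAC 10.46-fold (adjusted p 2.04e-09) and IFRH_SOLTU, an isoflavone reductase homologue well above background on 3 of 6 ZT0 arrays, 4.25-fold (adjusted p 2.47e-06). 5EAS1_NICAT rose by at least 2.07-fold (adjusted p 4.71e-07, and 0.0724 with normexp). PTR16_ARATH, well above background on 2 of 6 ZT0 arrays, rose by log2 2.16 and the phospholipase PLDA1_TOBAC rose 2.92-fold, with adjusted p 0.000306 and 0.000286 that became 0.0777 and 0.124 with slide as a block; both calls held in every other alternative run for named probes. POLC2_TOBAC, a calcium-binding pollen protein homologue, fell 3.58-fold (adjusted p 4.21e-06) and was well above background on 3 of 6 ZT14 arrays. In total 17754 probes differed, 8429 higher at ZT14 and 9325 lower, and 7412 with slide as a block.

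Over all 91 tests of lists and label groups, 13 passed with the preset correlation and none with an estimated one, where 3 had an unadjusted p under 0.05. Histones, proteasome and ubiquitin, phenylpropanoid and lignin enzymes, starch and sucrose enzymes, pollen proteins and the defence group passed in none of the 7 contrasts with all arrays and no block (lowest adjusted p 0.176, for defence between ZT14 and ZT0). In some tests that did not pass, median, mean and test differed in sign. RL15_PETHY, RS4_SOLTU, YCF68_SACOF, PSBC_TRACE, PSBK_SILLA, PSA6_TOBAC, RR3_OENEH and FENR2_TOBAC fall outside the naming rule and were chosen after their values were seen.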

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

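Of the tests weighed in this part, that of slide for the larger count at ZT6, the blocks for pairs, the splits that follow the pairs and the fit without the 3 arrays of lowest signal were chosen only after the result was seen. A difference between times in the side difference brought 9 results here, each by the moderated F-test: 2713 probes as a whole, and among named probes ABAH4_ARATH (adjusted p 0.0221), C71DK_TOBAC (0.00617), 5EAS1_NICAT (0.000571), PDR1_TOBAC (0.00113), RCA_SOLPN (0.000469), SNAK1_SOLTU (0.00564), CATA3_NICPL (0.00755) and MATK_POPAL (0.0446). CATA3_NICPL came here by its brighter probe, while its dimmer one had an adjusted p of 0.51 by the same test. For the 2713 probes, 100 splits by side within each time were counted, the real one included, each parting every pair at ZT0 and ZT14. Of these 1 gave as many, and the highest other gave 2430. Such splits stand for sides that do not differ at any time, not for a difference that stays the same over time. They therefore cannot decide whether chance gave the dependence on time. Splits drawn without regard to the pairs gave at most 1315.

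The first pattern is the larger number of side differences at ZT6. Compared with ZT14, the tables argue against slide, since with slide as a block 4913 probes passed at ZT6 and 943 at ZT14. For ZT0 this block cannot decide, as the side contrast there then rests on 1 abaxial array, replicate 1 on slide 2. The low-signal array abaxial ZT6 replicate 3 is argued against, since without it 4481 passed at ZT6, 267 at ZT0 and 1040 at ZT14. Abaxial ZT0 replicates 1 and 2 had lower signal still. Leaving them out leaves 1 abaxial array at ZT0, so low signal there cannot be weighed. Less spread between replicates at ZT6 than at ZT14 is argued against, as the median SD within the ZT6 groups was 1.16 times that within the ZT14 groups. Against ZT0 it was slightly less, 0.214 at ZT6 and 0.228 at ZT0. The fit pools the spread over all groups, so its median SE of 0.185 is the same at each time by construction. A smaller spread at ZT6 could thus not lower the SE there, which argues against this explanation for ZT0 too. The median absolute side difference was 0.149 at ZT0 and 0.258 at ZT6. With the pairs at ZT0 and ZT14 as a random block 5320 passed at ZT6, 3339 at ZT14 and 1195 at ZT0, and with a block for each pair at every time 7608, 2044 and 627, so part of the excess may come from variation that pairs share. A real difference between the sides at midday stays open beside it, as does how exactly the sides were cut at each time, which was not tested.

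The second pattern is that the adaxial side at ZT6 lay further along the change from ZT0 to ZT6: across probes, which are not independent, the side difference correlated with that change at 0.399 (Spearman 0.384, 0.331 to 0.431 with 1 array left out). The slide is argued against by 0.416 between the difference within slide 1 and the change within slide 2, which share no array. The low-signal array, abaxial ZT6 replicate 3, is argued against by 0.402 without it. Within 10 bins of mean signal over all arrays the median correlation was 0.426 (0.31 to 0.51). This cannot decide on a signal-dependent scale, as within a bin a probe's ZT6 signal still follows its change from ZT0. A candidate explanation is that the adaxial side ran ahead in a daily programme, but the same relation at ZT14, to the change from ZT6 to ZT14, was 0.0689 (Spearman 0.104, -0.0352 to 0.116 with 1 array left out). The bound set beforehand was 0.1, which lies inside that range, so being ahead at every time cannot be told apart from being ahead at ZT6 alone. A stronger adaxial response at ZT6 to light or warmth stays open, untested.

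The third pattern is the higher signal of 60 plastid- and mitochondrial-genome probes at ZT0 than at ZT6, with a median change of -1.23 and 59 of 60 below 0. By their labels several of these probes stand for the same gene, so the 60 are not independent. Slide is argued against by a median of -1.27 within slide 2, the low-signal arrays by -1.19 without them, and the scaling by a highest median of -0.835 under 3 other scalings. RNA quality, carried-over DNA and the priming of transcripts without a poly(A) tail were not tested and stay open beside a real daily change, which may act on both organelles.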

How the results depend on the processing

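The pair block within times, the random block for the pairs at ZT0 and ZT14 and the fit without the 3 arrays of lowest signal were chosen after seeing the data. No named probe changed direction in any alternative run for named probes, and no scaling moved the share of higher calls by over 10 percentage points. The larger direction still turned for ZT6 against ZT0 with normexp (8907 higher, 10415 lower), quantile normalization (10148, 10386) and the percentile over detected probes (9589, 10800), and for ZT14 against ZT6 with the last 2 (8191, 7397 and 8575, 7253). Between the sides, where the directions were near even, it turned at ZT6 with the percentile over detected probes (2726, 2623) and a floor (2796, 2724). At ZT0 it turned with quantile normalization (127, 111), the percentile over detected probes (111, 109), a floor (126, 123) and the authors' table (106, 104). All counts stayed within 1.5 times under normexp, quantile normalization, the percentile over detected probes, a floor, the authors' table, the filter on all 18 arrays, the trended robust prior and slide as a random block. Below only counts that moved further are given. In the order sides at ZT0, ZT6, ZT14, on average, at any time and dependence on time, an adjusted p under 0.01 gave 80, 2803, 321, 1312, 2241 and 1294 probes. A 2-fold minimum gave 1949 at ZT6, 387 at ZT14, 439 on average, 6888 for ZT6 against ZT0, 3569 for ZT14 against ZT6 and 5558 for ZT14 against ZT0. Array weights gave 9403 at ZT6, 1910 at ZT14, 8744 at any time and 4840 for dependence on time. Without the filter the counts were 125 at ZT0, 413 at ZT14, 1701 on average, 2778 at any time and 1559 for dependence on time. Fits of only the groups compared gave 50 at ZT0 and 327 at ZT14, as fewer arrays give the spread. Slide 1 alone gave 1772 at ZT6, slide 2 alone 2 at ZT0 and 668 at ZT6, and slide 3 alone 327 at ZT14. Slide as a fixed block gave 111 at ZT0, 3077 for ZT14 against ZT6 and 7412 for ZT14 against ZT0. Without the 3 low arrays 1003 passed at ZT0, 1488 at ZT14 and 4829 for dependence on time. Of 13 list calls 0 held with an estimated correlation. At ZT0 the fits with slide as a fixed block, with slide 2 alone and without the 3 low arrays each rest on 1 abaxial array. Except where the construction shows it, the cause was not tested.

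With 1 array left out the counts ran from 105 to 267 at ZT0, 3538 to 6074 at ZT6, 368 to 1067 at ZT14, 2063 to 3242 on average, 3058 to 5270 at any time and 1744 to 3211 for dependence on time. They ran from 19345 to 20672 for ZT6 against ZT0, 14295 to 16613 for ZT14 against ZT6 and 16416 to 18670 for ZT14 against ZT0. Over these, 60 of 1134 calls of named probes were lost.

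With replicate number as a block over all times no count moved by 1.5 times (290 at ZT0, 5747 at ZT6, 1146 at ZT14), 0 calls of named probes were lost and 14 list tests passed. A block for each pair within a time gave 627 at ZT0, 2044 at ZT14, 4403 on average, 6923 at any time and 4824 for dependence on time. It cannot test changes between times. With the pairs at ZT0 and ZT14 as a random block 19183 passed for ZT6 against ZT0, 14053 for ZT14 against ZT6 and 14999 for ZT14 against ZT0. The sides then gave 1195 at ZT0, 3339 at ZT14, 4750 on average, 7274 at any time and 4709 for dependence on time. No call of a named probe was lost with either form of pair block, and of the 4 list calls between the sides 4 held with the fixed one, where 6 passed. From ZT6 to ZT14, groups that did not pass with all arrays and no block passed with slide as a block, which rests on 1 array: nuclear photosynthesis (median -1.13, camera adjusted p 0.00474), mitochondrial-genome (0.68, 0.021) and plastid-genome proteins (0.339, 0.02). With an estimated correlation and no block their camera adjusted p-values were 0.834, 0.922 and 0.968. Nuclear photosynthesis proteins also passed with replicate number as a block (0.0427). At ZT6 same-numbered sides correlated at 0.000615 to 0.316, and 2 of 3 correlated best with their own number, a hint from the data and not the design; there the pair block gave 7608. Signal limits the probes: on each array 45.24% to 53.22% were well above background.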

Other observations

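In this part the splits that follow the pairs and the counts of shared direction were chosen only after the result was seen. A set of 73 probes differed between the sides at all 3 times in 1 direction, 45 higher adaxially and 28 higher abaxially, and 12 more differed at all times in mixed directions. Side differences at ZT0 and ZT14, from separate arrays, correlated across probes at 0.366 (Spearman 0.255), those at ZT0 and ZT6 at 0.275 (0.243), and those at ZT14 and ZT6 at -0.0151 (-0.109). Calls at ZT0 and ZT14 shared 61 probes higher adaxially and 51 higher abaxially, where independent lists would share 1.4 and 1.57, and 1 probe was opposite.

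Other labelled genes, named here after their values were seen, passed the test between times and not between the sides at ZT6. PP2A_TOBAC and PP2A5_TOBAC, which the name pattern of a phloem list took in, are protein phosphatase 2A subunits and not phloem lectins. They differed between the sides at ZT6 by -0.02 and -0.10 (limma adjusted p 0.981 and 0.689). The xylem peptidase XCP1_ARATH differed by 0.29 (limma adjusted p 0.493). From ZT6 to ZT14 PP2A5_TOBAC fell by 0.92 (adjusted p 5.3e-06) and XCP1_ARATH fell by 0.75 (adjusted p 0.00365). OPR3_SOLLC, an enzyme of jasmonate synthesis, rose by 0.81 from ZT0 to ZT14 (adjusted p 2.94e-06). Of 4 histones 3 rose from ZT0 to ZT6, with a median of 0.852, and the group did not pass (adjusted p 0.303). 4CL1_TOBAC, an enzyme of phenylpropanoid and lignin synthesis, rose by 1.26 from ZT0 to ZT6 (adjusted p 7.48e-07).

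For the sides at a single time the 6 arrays allow 10 splits, too few for a share under 0.05. The real split gave 211 probes at ZT0 and the highest other 2, 5326 and 1 at ZT6, and 865 and 6 at ZT14. Among splits that part all 3 pairs, as the real one does, the highest other was 1 at ZT0 and 1 at ZT14. With 100 splits that part every pair at ZT0 and ZT14, chance is excluded for the average over times (2657, highest other 1497) and a difference at any time (4375, 3127); splits drawn without regard to the pairs gave at most 1188 and 2400. With these pairs kept whole and the ZT6 arrays taken as unpaired, 28 splits exclude chance for ZT6 against ZT0 (20455, highest other 67) and ZT14 against ZT6 (15788, 0). For ZT14 against ZT0 they number 10, too few for a share under 0.05 (17754, 81). Were the ZT6 sides paired too, the splits for the contrasts with ZT6 would be as few and could not exclude chance. In each of these comparisons 1 split, the real one, gave as many. Splits drawn without regard to the pairs gave at most 13582, 8499 and 9871 between times.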
